A study of Homo sapiens with 15 samples.

How the data were processed

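RNA was measured by poly(A) sequencing in HEK293T cells at passages 7 to 11, transfected with Lipofectamine and harvested after 48 h, with RNA purified on RNeasy columns. The deposited values were raw read counts per Ensembl gene, which the authors made with CASAVA 1.8, TopHat2 2.0.13 and Bowtie2 2.2.1 on the hg19 genome, followed by HTSeq. The HTSeq version, the strand setting and the annotation are not given in the sources used here, so values of genes that overlap or lie antisense to another are uncertain. Groups were taken from the labels: GFP, WT, FL, R151A and D247A, with 3 libraries each, numbered 1 to 3 in the order of listing. Of 38818 identifiers, 28724 had a current symbol, 7702 were found by GENCODE 29 alone and 2392 had no name; the unnamed held 0.796 to 1.12% of the counts. GENCODE 29, a GRCh38 annotation, was used for names, gene types, lengths, exon numbers and GC content, and no coordinates are given.

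Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with the groups, robust quasi-likelihood dispersion, all 15 libraries), with 10 pairwise comparisons and 1 test of any difference among the 5 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and 23941 genes were tested. CPM values in the text are TMM-normalized group means with their SD. The median SE of a log2 fold change was 0.116 for genes at a mean CPM of at least 5. Over the 15 pairs of libraries within a group, the chi-square per degree of freedom for genes with at least 100 counts in the pair was 16.8 to 103, so the spread between libraries exceeded counting error.

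Named genes followed a rule: among called genes with a symbol, a mean CPM of at least 5 and no overlap between the 3 libraries of each group, the 8 with the largest rise and the 8 with the largest fall in WT vs GFP and FL vs WT, and 5 and 5 in the other comparisons. By chance 10% of genes would have no overlap between 3 libraries and 3. TARDBP was added, as were up to 4 genes with the smallest adjusted p from each list that passed its test or had at least 2 called genes, and such genes could be followed into other comparisons. Some genes that the rule picks are not reported here. The 32 gene lists covered translation, mitochondria, proteostasis, stress and inflammatory responses, RNA processing, targets of TDP43 loss, histones, the cell cycle, metabolism, nuclear transport, disease and neuronal genes, and markers of fibroblast, blood, epithelial and liver cells. Lists were tested with limma 3.58.1 by camera (preset correlation 0.01, then an estimated correlation) and fry, adjusted over the 32 lists of a comparison, and counts were also adjusted over each list alone.

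WT-selective genes were called in WT vs GFP and in FL vs WT with opposite signs. The share of the WT response took genes called in WT vs GFP without 1 WT and 1 GFP library, weighted each gene's log2 change from the held-out GFP library by its fitted WT change, and divided the sum for a variant's library by that for the held-out WT library; the median over 9 choices of held-out libraries is given. The overlap that comes from shared GFP libraries was simulated for unchanged groups, 100 times for fold changes and 20 times for calls. The alternatives were RLE size factors, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, 1 surrogate variable (sva 3.50.0), a fit of the 2 groups alone, limma-voom, DESeq2 1.42.0, TARDBP left out and each library left out. The named-gene rule, the gene lists and these alternatives were fixed before the data were examined. BLAST 2.17.0 compared AC012485.1 with TARDBP.

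The methods were tested on simulated data. For WT vs GFP, the fit found 10% of 50 genes changed 1.25-fold, 82% of 50 changed 1.5-fold, 96% of 50 changed 2-fold and 100% of 50 changed 4-fold among 23374 tested, and 6 unchanged genes made up 4% of its calls. For R151A vs FL it found 12, 82, 98 and 100% of 50 genes each, and 8 unchanged genes made up 5.19% of its calls. In both simulations only genes at a mean CPM of at least 5 were changed, and each gene and library was drawn independently. True shares of 0, 30 and 60% were measured as -0.28, 29.94 and 59.55%. A simulated list of 60 raised genes passed camera and a list of 60 unchanged genes did not. Splicing, polyadenylation sites and transcript isoforms were not analysed here, since the counts are per gene.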

Results

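Poly(A) RNA was sequenced from HEK293T cells, a human embryonic kidney line, 48 h after transient transfection with 1 of 5 constructs. TDP43, encoded by TARDBP, is an RNA-binding protein of the nucleus with a pair of RNA recognition motifs. The constructs were EGFP alone (GFP), wild-type TDP43 fused to EGFP (WT), the RNA-binding-deficient double mutant F147L and F149L (FL), and the single substitutions R151A and D247A. The series title names an intramolecular salt bridge that links the recognition motifs. Each group had 3 libraries, 15 in all, with 51676824 to 83911051 gene counts per library, and 23941 of 38818 genes passed the expression filter. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. GFP library 3 stood apart from the other GFP libraries: the chi-square per degree of freedom between pairs was 103 and 100.1 with GFP libraries 1 and 2, and 35.2 between those. D247A library 3 had 89.8 and 64.6 with D247A libraries 1 and 2, which had 25.5 between them.

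TARDBP counts include both the transgene and the endogenous mRNA, and they were far above the control in each TDP43 group. The level was 632 ± 39.8 CPM (normalised counts scaled to library size; mean ± SD, n = 3) in GFP, 62305 ± 21068 in WT, 80734 ± 22014 in FL, 65728 ± 25050 in R151A and 105639 ± 16100 in D247A. Against GFP the log2 fold change was 6.62 (SE 0.40, adjusted p = 1.49e-06) in WT, 7.00 (SE 0.41) in FL, 6.70 (SE 0.41) in R151A and 7.38 (SE 0.42) in D247A by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No pair of TDP43 groups differed in TARDBP past the threshold. The adjusted p was 0.472 for FL vs WT, 0.895 for R151A vs WT, 0.171 for D247A vs WT, 0.693 for D247A vs FL and 0.277 for R151A vs D247A. Still, each D247A library, from 88499.8 CPM, was above each WT library, up to 81923.8, and each R151A library, up to 88458. D247A was 1.70-fold WT (log2 fold change 0.762, SE 0.318). The effect of this higher level on comparisons of D247A with WT and R151A was not tested. TARDBP took 3.89 to 11.5% of the counts in libraries with a TDP43 construct and 0.0606 to 0.068% in GFP. AC012485.1, a processed transcript that aligned to TARDBP at 93.9% identity over 472 bases, had a ratio to TARDBP that varied 1.61-fold between the lowest and highest of the 12 TDP43 libraries, where the TARDBP share varied 2.96-fold, and is reported as uncertain, since it may share reads with TARDBP. Its log2 fold change against GFP was 6.22 in WT, 6.61 in FL, 6.25 in R151A and 7.07 in D247A. The R151A call was lost with limma-voom (adjusted p = 0.0734).

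**Figure D1:**
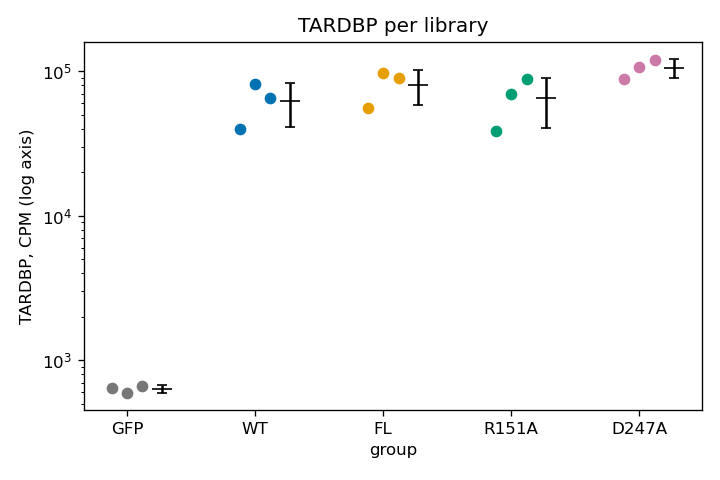
TARDBP in CPM (log axis) in each of the 15 libraries by group, with the group mean and SD (n = 3) as a bar beside the points. The GFP libraries lie between 589 and 667.6 CPM and the TDP43 libraries between 38870.8 and 120445.5 CPM.

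Expression of wild-type TDP43 against EGFP alone asks what added TDP43 does to the transcriptome. MAP1A, a microtubule-associated protein, went from 10.9 ± 1.69 CPM in GFP to 79.5 ± 21 CPM in WT (mean ± SD, n = 3), a log2 fold change of 2.87 (SE 0.17, adjusted p = 3.60e-09). KCND1, a voltage-gated potassium channel subunit, rose by 2.74 (SE 0.21) on the log2 scale, and CTSK, the protease cathepsin K, by 2.33 (SE 0.26). PPP1R10, a nuclear regulatory subunit of protein phosphatase 1, rose by 2.34 (SE 0.31), from 19.2 ± 4.82 to 96.9 ± 35.9 CPM. RHBDL1, a rhomboid-like protease, rose by 1.96 (SE 0.21), and SLITRK3, a synaptic adhesion protein, by 1.84 (SE 0.25). CCN1, a secreted matrix protein of the immediate early response, had a log2 fold change of -2.08 (SE 0.16, adjusted p = 4.72e-08), from 74.8 ± 10.3 to 17.6 ± 2.84 CPM. DNAJB1, a co-chaperone of HSP70, had -1.40 (SE 0.18), and HSPA5, the HSP70 chaperone of the endoplasmic reticulum (ER), had -1.63 (SE 0.36). SNHG1, a host gene of small nucleolar RNAs, fell by 1.54 (SE 0.38), a call that was lost without WT library 2 (adjusted p = 0.0673). The small nucleolar RNA gene SNORA73B fell by 2.198 (SE 0.60), the histone gene H2BC21 by 2.16 (SE 0.56), GLIPR1 by 1.69 (SE 0.47) and the translation initiation factor EIF4A1 by 1.56 (SE 0.50). These 4 calls were lost without WT library 1, WT library 2 or GFP library 3, with adjusted p without WT library 2 of 0.0862, 0.0773, 0.104 and 0.155. Small RNA and histone genes are reported as uncertain throughout. They share sequence with others, and how poly(A) selection affected their counts was not tested. In all, 5834 genes passed, 3266 higher and 2568 lower in WT, and 2871 of them changed by at least 1.5-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without WT library 2, which had the highest TARDBP level of the 3 WT libraries at 81923.8 CPM, the count was 3453.

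Of 77 ribosomal protein genes tested, 75 fell and 0 rose over all genes tested, and 77 fell adjusted over the list alone; RPS3 had a log2 fold change of -0.72 and RPL34 -0.84. The list's median was -0.49. For ribosomal protein genes camera gave adjusted p = 1.20e-35 (adjusted p = 0.290 with an estimated correlation). Ribosomal protein genes have many processed pseudogenes, so their counts may be split. Of 77 nuclear genes of oxidative phosphorylation, 44 fell (54 adjusted over the list alone), among them ATP5MG with -1.05 and NDUFS3 with -0.74. For oxidative phosphorylation camera gave adjusted p = 4.19e-19 (adjusted p = 0.312 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 1 rose and 0 fell, with 0 called adjusted over the list alone; all 13 had a positive log2 fold change, with a median of 0.38, and the list did not pass camera (adjusted p = 0.105). Of 73 mitochondrial ribosomal protein genes, 27 fell and 4 rose (30 and 6 adjusted over the list alone), with MRPS5 at -0.59 and MRPL53 at 1.41. For mitochondrial ribosomal protein genes camera gave adjusted p = 9.94e-04 (adjusted p = 0.678 with an estimated correlation). Of 21 glycolysis genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone), including the enzymes GPI with -0.55 and LDHA with -0.56. For glycolysis genes camera gave adjusted p = 1.83e-06 (adjusted p = 0.264 with an estimated correlation). Of 25 cholesterol synthesis genes, 6 fell and 1 rose, the same numbers adjusted over the list alone, with FDFT1, squalene synthase, at -0.76. For cholesterol synthesis genes camera gave adjusted p = 0.0295 (adjusted p = 0.678 with an estimated correlation).

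The 2 cell cycle lists went opposite ways in WT. Of 30 genes of G2 and M, 19 rose and 1 fell (23 and 1 adjusted over the list alone), led by the mitotic kinesin KIF20A, which went from 95.9 ± 8.03 to 320 ± 70.8 CPM, a log2 fold change of 1.74 (SE 0.13). The proliferation marker MKI67 rose by 1.40 (SE 0.11), HMMR, a spindle protein, by 0.88 and KIF11, another mitotic kinesin, by 0.68. The list's median was 0.48. For genes of G2 and M camera gave adjusted p = 3.45e-14 (adjusted p = 0.264 with an estimated correlation). Of 29 genes of the G1 to S transition, 17 fell and 0 rose (19 adjusted over the list alone), with RRM2, a ribonucleotide reductase subunit, at -0.73 and the replication factors GINS2 at -0.53 and MCM7 at -0.42. For G1 to S genes camera gave adjusted p = 1.10e-06 (adjusted p = 0.332 with an estimated correlation). Of 20 p53 targets, 5 rose (10 adjusted over the list alone), including RRM2B with 0.99 and the stress-response gene SESN1 with 0.79. For p53 targets camera gave adjusted p = 0.0125 (adjusted p = 0.700 with an estimated correlation).

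Of 22 heat shock genes, 12 fell and 0 rose (14 adjusted over the list alone), including HSPH1 with -1.04 and HSP90AA1 with -0.64; HSPA1B, with -1.39, has a near-identical neighbour and its reads may be shared. The camera adjusted p was 9.19e-07 (adjusted p = 0.264 with an estimated correlation). Of 22 genes of the unfolded protein response of the ER, 11 fell and 3 rose (14 and 3 adjusted over the list alone), with the folding factors SDF2L1 at -1.11 and PDIA3 at -0.70. For the unfolded protein response camera gave adjusted p = 4.37e-04 (adjusted p = 0.633 with an estimated correlation). In the integrated stress response list 5 of 27 fell and 1 rose, as adjusted over the list alone, with ATF3 at -1.23 and SLC3A2 at 0.79. For the integrated stress response camera gave adjusted p = 0.0326 (adjusted p = 0.700 with an estimated correlation). Immediate early genes, which respond to growth signals, fell in 9 of 29 cases (9 adjusted over the list alone), with CCN1, the phosphatase DUSP1 at -1.29 and JUN at -0.54. For immediate early genes camera gave adjusted p = 3.04e-04 (adjusted p = 0.264 with an estimated correlation).

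RNA-processing genes moved in both directions in WT. Of 43 core spliceosome genes, 20 fell and 3 rose (25 and 4 adjusted over the list alone), with the U2 protein SNRPA1 at -0.67 and the U2-associated SF3B4 at 0.60. For core spliceosome camera gave adjusted p = 2.08e-04 (adjusted p = 0.401 with an estimated correlation). Of 28 hnRNP genes, TARDBP left out, 11 fell and 4 rose (13 and 4 adjusted over the list alone), with HNRNPA1 at -0.78 and PTBP1 at -0.53. For hnRNP genes camera gave adjusted p = 0.00470 (adjusted p = 0.426 with an estimated correlation). Among 37 SR proteins and splicing regulators 10 fell and 3 rose (11 and 4 adjusted over the list alone), and SON, a scaffold of nuclear speckles, rose by 0.99 (SE 0.10); the list did not pass camera (adjusted p = 0.281). Of 22 targets of nonsense-mediated decay, 10 fell and 2 rose (12 and 3 adjusted over the list alone), with SNHG6 at -1.07. For nonsense-mediated decay targets camera gave adjusted p = 7.52e-04 (adjusted p = 0.264 with an estimated correlation). Of 29 genes known to be misprocessed when TDP43 is lost, 5 fell and 1 rose, as adjusted over the list alone, including DNMT3A with -0.49 and GPSM2 with 0.36; the list did not pass camera (adjusted p = 0.377). Gene counts do not show the splicing changes by which that list was drawn up. The following lists did not pass camera in WT vs GFP, though single members did, and list p-values are those of camera unless fry is named. Of 35 interferon-response genes 5 rose and 1 fell (5 and 0 adjusted over the list alone; list adjusted p = 0.143; 0.0453 by fry, past the threshold), with IFIT5 at 0.98, and of 17 NF-kB genes 3 rose and 1 fell, as adjusted over the list alone (list adjusted p = 0.622), with TNFAIP3 at 1.01. Of 43 nuclear transport genes 10 rose and 10 fell, as adjusted over the list alone (list adjusted p = 0.804), with the importin KPNA2 at 0.92 and the transport GTPase RAN at -0.81. Of 28 motor neuron disease genes 5 rose and 8 fell (6 and 9 adjusted over the list alone; list adjusted p = 0.538), with CCNF at 1.13 and SOD1 at -0.61. Of 37 autophagy genes 7 rose and 8 fell (8 and 9 adjusted over the list alone; list adjusted p = 0.538), of 30 proteasome genes 4 rose and 5 fell, as adjusted over the list alone (list adjusted p = 0.622), and of 25 stress granule genes 3 rose and 5 fell (3 and 6 adjusted over the list alone; list adjusted p = 0.281), with PUM2 at 0.81 and PABPC1 at -0.71. Of 24 neuronal genes 4 rose and 3 fell, as adjusted over the list alone (list adjusted p = 0.694), of 8 nuclear retained RNAs 1 rose and 2 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.377), and of 17 replication-dependent histone genes 2 rose and 7 fell, as adjusted over the list alone (list adjusted p = 0.0660). The histone counts are uncertain in these poly(A) libraries.

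Of the 32 lists 15 passed camera in WT vs GFP, 2 up and 13 down, and 0 passed with an estimated correlation. The markers of epithelial cells, fibroblasts, hepatocytes and blood cells, tested as signs of another cell type, did not pass camera, while the epithelial markers passed fry (adjusted p = 0.0266). Of 13 fibroblast markers 2 rose and 0 fell (list adjusted p = 0.252), of 9 blood cell markers 1 rose and 0 fell (0.702) and of 8 epithelial markers 2 rose and 0 fell (0.281), with the same numbers adjusted over the list alone. Of 5 hepatocyte markers 0 rose and 1 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.622).

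**Figure D2:**
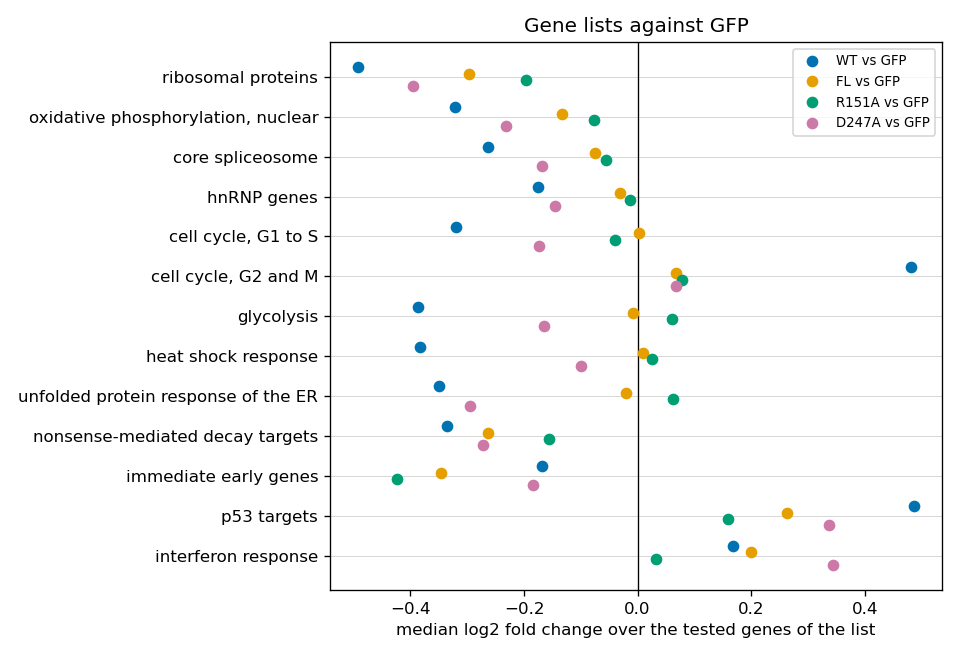
Median log2 fold change over the tested genes of 13 gene lists (x axis) in each TDP43 group against GFP; each point is 1 list in 1 comparison. Ribosomal protein genes lie at -0.49 in WT, -0.30 in FL, -0.20 in R151A and -0.40 in D247A, while genes of G2 and M lie at 0.48 in WT and between 0.07 and 0.08 in the other 3 groups.

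The FL double mutant against EGFP alone asks what TDP43 that is deficient in RNA binding does. CCN1 fell, with a log2 fold change of -1.48 (SE 0.15, adjusted p = 2.89e-05) and a level of 26.8 ± 3.08 CPM against 74.8 ± 10.3 CPM in GFP (mean ± SD, n = 3). NYNRIN, a gene derived from a retroviral element, rose by 0.97 (SE 0.15), IL18BP, which encodes the interleukin-18 binding protein, by 0.84 (SE 0.15), and the transcription factor gene CSRNP3 by 0.82 (SE 0.16). AC083843.2, a long noncoding RNA, rose by 0.93 (SE 0.17). The receptor tyrosine kinase gene EPHA8 fell by 0.98 (SE 0.18), the transcription factor gene CEBPB by 0.86 (SE 0.17), the collagen gene COL26A1 by 0.83 (SE 0.15) and KCTD15 by 0.62 (SE 0.12). In all 34 genes passed, 20 higher and 14 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), TARDBP and AC012485.1 among them, and 2373 had an unadjusted p under 0.05. Of these named genes, CCN1 kept its call without any 1 library, while NYNRIN lost it without FL library 3 (adjusted p = 0.0523) and each of the other 7 lost it without FL library 2 (adjusted p from 0.074 to 0.254). Some of these 7 also lost it without GFP libraries 1 or 2 or FL libraries 1 or 3 (adjusted p from 0.056 to 0.24). The count was 390 without GFP library 3 (79.5% higher), 17 without GFP library 1, 16 without GFP library 2, and 18, 14 and 11 without FL libraries 1, 2 and 3; DESeq2 called 188 genes, 43.6% of them higher against 58.8% here.

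By gene group, immediate early genes were the 1 list of 32 that passed in FL vs GFP with both forms of the camera test. In the camera test, immediate early genes had adjusted p = 1.72e-14 (adjusted p = 0.0178 with an estimated correlation). Of its 29 genes, 1 fell over all genes tested, CCN1, and 10 fell adjusted over the list alone, with a list median of -0.35; the values were -1.04 for CCN2 and -0.48 for DUSP1. Ribosomal protein genes had a median of -0.30, with 0 of 77 called over all genes tested and 70 lower adjusted over the list alone. Camera applied to ribosomal protein genes gave adjusted p = 4.56e-47 (adjusted p = 0.296 with an estimated correlation). For genes of G2 and M the median was 0.07, with 0 of 30 called. Testing genes of G2 and M by camera gave adjusted p = 0.0380 (adjusted p = 0.763 with an estimated correlation). In total 11 of 32 lists passed camera, 5 up and 6 down.

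The R151A variant was also set against EGFP alone. HSPA6, a stress-inducible HSP70 chaperone, went from 95.8 ± 45.9 CPM in GFP to 5.21 ± 1.35 CPM in R151A (mean ± SD, n = 3), a log2 fold change of -4.20 (SE 0.38, adjusted p = 5.78e-04); it has a near-identical pseudogene, so its reads may be shared. CCN1 fell by 1.27 (SE 0.15), from 74.8 ± 10.3 to 30.9 ± 5.89 CPM, the potassium channel gene KCNC1 by 0.72 (SE 0.14), the transcriptional repressor ZBTB7A by 0.54 (SE 0.10) and BAG3, an HSP70 co-chaperone, by 0.53 (SE 0.09). MC1R, the melanocortin receptor gene, rose by 1.75 (SE 0.23), MAEA, a ubiquitin ligase subunit, by 0.77 (SE 0.12), NYNRIN by 0.85 (SE 0.15) and CERS6, a ceramide synthase, by 0.49 (SE 0.09). In all 19 genes passed, 9 higher and 10 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 1761 had an unadjusted p under 0.05. HSPA6 lost its call in a fit of these 2 groups alone (adjusted p = 0.0764), while MC1R and CCN1 kept theirs without any 1 library. MAEA lost its call without R151A library 3 (adjusted p = 0.0714); BAG3, KCNC1, ZBTB7A, NYNRIN and CERS6 lost theirs without R151A library 2 (adjusted p from 0.0711 to 0.211) and without GFP library 2 (adjusted p from 0.0535 to 0.2). Some of these also lost it without GFP library 1 (adjusted p up to 0.336), R151A library 1 (up to 0.211) or R151A library 3 (up to 0.382). The count was 428 without GFP library 3 (69.4% higher), 11 without R151A library 2 and 12 without R151A library 3; DESeq2 called 124 genes, 33.1% of them higher against 47.4% here.

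As in FL, the immediate early list was the 1 list that passed both forms of the camera test in R151A vs GFP (adjusted p = 7.02e-20; adjusted p = 0.00480 with an estimated correlation), with 1 of 29 genes lower over all genes tested and 15 lower adjusted over the list alone. Its median log2 fold change was -0.42. In the heat shock list HSPA6 and BAG3 fell and 0 of 22 rose (2 fell and 2 rose adjusted over the list alone; list adjusted p = 0.318). Ribosomal protein genes had a median of -0.20 with 0 of 77 called, also adjusted over the list alone. For ribosomal protein genes camera gave adjusted p = 4.77e-23 (adjusted p = 0.592 with an estimated correlation). Lists that passed camera numbered 13, 5 up and 8 down.

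The D247A variant against EGFP alone changed many genes, some by as much as WT did. KCND1 reached 26.6 ± 6.40 CPM in D247A, 26.6 ± 6 CPM in WT and 3.98 ± 0.339 CPM in GFP (mean ± SD, n = 3), a log2 fold change of 2.74 (SE 0.21, adjusted p = 2.01e-07), and CTSK rose by 2.56 (SE 0.26). SHOX2, a homeobox transcription factor, rose by 1.66 (SE 0.16), MC1R by 1.31 (SE 0.23) and SRSF3, a splicing factor, by 0.95 (SE 0.09), from 294 ± 8.77 to 566 ± 86.5 CPM. HSPA5 had -1.31 (SE 0.36), CCN1 -1.62 (SE 0.15), INPP5A, an inositol phosphatase, -1.17 (SE 0.16), and DNAH1, a dynein heavy chain, -1.07 (SE 0.20). The HSPA5 call was lost without D247A library 1, 2 or 3 (adjusted p = 0.171, 0.126 and 0.0536) and without GFP library 2 or 3 (adjusted p = 0.103 and 0.119). HSPA6 had -2.01 (SE 0.34), a call lost in a fit of the 2 groups alone (adjusted p = 0.0755). In all 2117 genes passed, 1268 higher and 849 lower, 810 of them by at least 1.5-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The count was 1032 without D247A library 1, 1086 without D247A library 2 and 1222 without GFP library 2.

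Several groups lower in WT were lower in D247A as well. Ribosomal protein genes fell in 67 of 77 cases (76 adjusted over the list alone), with RPS27A at -0.60 (camera, adjusted p = 5.43e-43; adjusted p = 0.415 with an estimated correlation), and 20 of 77 nuclear genes of oxidative phosphorylation fell (38 adjusted over the list alone), with ATP5MG at -0.63. In the camera test, oxidative phosphorylation had adjusted p = 2.02e-18 (adjusted p = 0.415 with an estimated correlation). In the list of the unfolded protein response 8 of 22 fell and 0 rose (12 adjusted over the list alone), with HERPUD1, a factor of ER-associated degradation, at -0.67. Camera applied to the unfolded protein response gave adjusted p = 2.85e-05 (adjusted p = 0.415 with an estimated correlation). Core spliceosome genes fell in 9 of 43 cases (14 fell and 2 rose adjusted over the list alone), with SNRPF at -0.48. Testing core spliceosome by camera gave adjusted p = 4.84e-05 (adjusted p = 0.415 with an estimated correlation). Of 35 interferon-response genes 6 rose (7 adjusted over the list alone), including IFIT5 with 0.94 and IFI44L with 1.46. For interferon-response genes camera gave adjusted p = 7.38e-05 (adjusted p = 0.415 with an estimated correlation). The G2 and M list did not pass camera, with 2 of 30 higher and 1 lower (4 and 2 adjusted over the list alone; adjusted p = 0.571), and KIF20A was at 105 ± 12.4 CPM. Autophagy genes moved both ways, 3 higher and 5 lower of 37, as adjusted over the list alone, with ULK1, an initiating kinase, at 0.90 and the lysosomal membrane protein LAMP1 at -0.62 (list adjusted p = 0.475). In total 14 of 32 lists passed camera, 2 up and 12 down, and 0 with an estimated correlation.

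**Figure D3:**
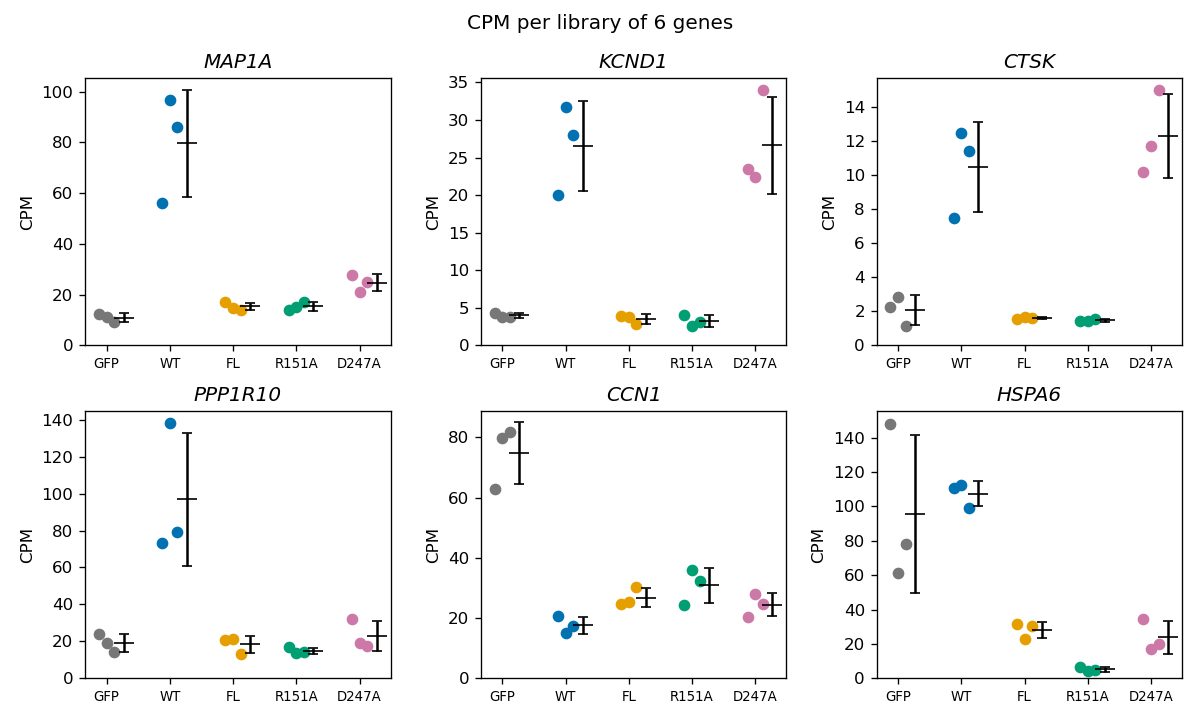
CPM of MAP1A, KCND1, CTSK, PPP1R10, CCN1 and HSPA6 in each of the 15 libraries by group, with the group mean and SD (n = 3) as a bar beside the points. KCND1 averages 26.6 CPM in WT and in D247A and 3.22 to 3.98 CPM in the other 3 groups, while CCN1 averages 74.8 CPM in GFP and 17.6 to 30.9 CPM in the others.

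The comparison of FL with WT asks which changes in WT go with RNA binding. KCND1 was lower in FL at a log2 fold change of -2.92 (SE 0.21, adjusted p = 2.96e-08), CTSK at -2.70 (SE 0.26), PPP1R10 at -2.39 (SE 0.31) and MAP1A at -2.37 (SE 0.17). HSPA6 was also lower, at -1.93 (SE 0.34) and 28.2 ± 4.67 against 108 ± 7.13 CPM (mean ± SD, n = 3). The WT libraries of HSPA6 lay within the range of the GFP libraries, 61.4 to 148 CPM. Its difference is therefore not the loss of a change from GFP to WT. The long noncoding RNA MGC12916 was higher in FL by 1.51 (SE 0.19), SLC9A9, a sodium and proton exchanger, by 1.29 (SE 0.21), P4HA1, a collagen prolyl hydroxylase, by 1.22 (SE 0.20) and NUDT10, a hydrolase, by 1.11 (SE 0.18). HSPA8, a constitutive HSP70 chaperone, was higher by 1.14 (SE 0.28), the nuclear RNA NEAT1 by 1.11 (SE 0.29), the kinase UHMK1 by 1.06 (SE 0.25) and AL359922.2, an antisense RNA whose value is uncertain without the strand setting, by 1.08 (SE 0.26). LCMT2 was lower, at -1.95 (SE 0.31) and the histone gene H2BC15 at -1.81 (SE 0.22), a value that is uncertain as for other histone genes. In all 4531 genes passed, 1967 higher and 2564 lower in FL (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Without WT library 2 the calls of HSPA8, NEAT1 and UHMK1 were lost (adjusted p = 0.0736, 0.101 and 0.0511), and those of HSPA8 and NEAT1 without FL library 3 (0.0697 and 0.0920); NEAT1 also lost it without FL library 1 (0.0678) and WT library 3 (0.0536). The count was 2399 without WT library 2 and 2674 without FL library 3. Of the 5834 genes called in WT vs GFP, 3488 (59.8%) were also called against FL in the same direction, 2039 higher and 1449 lower in WT; this WT-selective list was chosen on these libraries, so it is not independent evidence of its direction. The list held 1753 genes without WT library 2 and 2287 without FL library 3.

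By group, 18 of 30 genes of G2 and M were lower in FL than in WT and 0 higher (22 and 2 adjusted over the list alone), with KIF20A at -1.64 and CCNB1, cyclin B1, at -0.60. For genes of G2 and M camera gave adjusted p = 2.32e-11 (adjusted p = 0.463 with an estimated correlation). Genes of the G1 to S transition were higher in 16 of 29 cases and lower in 0 (19 and 2 adjusted over the list alone; adjusted p = 3.02e-07; adjusted p = 0.488 with an estimated correlation). Of 21 glycolysis genes 11 were higher and 1 lower (16 and 1 adjusted over the list alone), with GPI at 0.59 and the lactate transporter SLC16A3 at -1.51. In the camera test, glycolysis genes had adjusted p = 8.50e-07 (adjusted p = 0.463 with an estimated correlation). Heat shock genes were higher in 10 of 22 cases and lower in 1 (14 and 2 adjusted over the list alone), with HSP90AB1 at 0.56. For heat shock genes camera gave adjusted p = 8.50e-07 (adjusted p = 0.463 with an estimated correlation). Cholesterol synthesis genes were higher in 9 of 25 cases, as adjusted over the list alone, with SREBF2, a transcriptional regulator of the pathway, at 0.79. Camera applied to cholesterol synthesis genes gave adjusted p = 2.50e-04 (adjusted p = 0.529 with an estimated correlation). Among mitochondrially encoded mRNAs, 3 of 13 were lower, as adjusted over the list alone, including MT-ND3 at -1.09, a call lost without FL library 1 or 3 (adjusted p = 0.0527 and 0.0607; list adjusted p = 0.00300; adjusted p = 0.672 with an estimated correlation). Passing lists numbered 12, 10 up and 2 down, with 0 at an estimated correlation.

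The comparison of R151A with WT tested what the loss of this arginine does to the WT response. HSPA6 was lower in R151A at a log2 fold change of -4.37 (SE 0.39, adjusted p = 1.89e-05). Its WT libraries, at 99.3 to 112 CPM, lay within the range of the GFP libraries, at 61.4 to 148 CPM. This difference is therefore not the loss of a change from GFP to WT. KCND1 was lower in R151A at -3.04 (SE 0.21), CTSK at -2.83 (SE 0.27), PPP1R10 at -2.70 (SE 0.32) and MAP1A at -2.37 (SE 0.17). H2BC21 was higher by 1.84 (SE 0.56), GLIPR1 by 1.59 (SE 0.47) and SNHG1 by 1.47 (SE 0.38). MGC12916 was higher by 1.63 (SE 0.19), and HSPA5 by 1.48 (SE 0.36), a call lost without WT library 2 (adjusted p = 0.0503). Without WT library 2 the adjusted p was 0.136 for H2BC21, 0.130 for GLIPR1 and 0.0829 for SNHG1; all 3 calls were also lost without WT library 1 (0.105, 0.0928 and 0.0536), and those of H2BC21 and GLIPR1 without R151A library 1 (0.0919 and 0.088) or 2 (0.0922 and 0.0711). Ribosomal protein genes were higher in R151A in 43 of 77 cases (60 adjusted over the list alone; adjusted p = 6.51e-14; adjusted p = 0.504 with an estimated correlation), glycolysis genes in 17 of 21 with 1 lower (19 and 1 adjusted over the list alone; adjusted p = 6.25e-08; adjusted p = 0.442 with an estimated correlation). Of 22 genes of the unfolded protein response 12 were higher and 3 lower (15 and 4 adjusted over the list alone), with PDIA6 at 0.83. For the unfolded protein response camera gave adjusted p = 1.37e-05 (adjusted p = 0.442 with an estimated correlation). Of 30 genes of G2 and M 18 were lower and 1 higher (21 and 1 adjusted over the list alone), with KIF20A at -1.60. Tested as a list, genes of G2 and M had adjusted p = 1.37e-09 (adjusted p = 0.442 with an estimated correlation). In all 5607 genes passed, 2376 higher and 3231 lower in R151A (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3223 without WT library 2. Of the 3488 WT-selective genes, 3319 (95.2%) were called in R151A vs WT against the WT direction; both lists use the same WT libraries. Camera called 11 of the 32 lists, 9 up and 2 down, and 0 with an estimated correlation.

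The comparison of D247A with WT asks which of the WT changes differ in this variant. KCND1 and CTSK had log2 fold changes of 0.00 (SE 0.19) and 0.23 (SE 0.24) and did not pass (adjusted p = 0.997 and 0.622). MAP1A was lower in D247A than in WT at -1.69 (SE 0.17, adjusted p = 2.95e-06) and above GFP by 1.18 (SE 0.17). PPP1R10 was lower, at -2.08 (SE 0.31), RHBDL1 at -1.93 (SE 0.21), HSPA6 at -2.18 (SE 0.34), H2BC15 at -1.66 (SE 0.21) and KIF20A at -1.60 (SE 0.13). The WT libraries of HSPA6 lay within the range of the GFP libraries, so its difference is not the loss of a change from GFP to WT. Higher in D247A were PCK1, a gluconeogenic enzyme, by 1.58 (SE 0.29), and the ubiquitin ligase genes FBXO30, by 1.12 (SE 0.13), and RNF146, by 1.10 (SE 0.14). ANXA1, a phospholipid-binding annexin, was higher by 1.34 (SE 0.32) and the long noncoding RNA LINC01605 (ENSG00000253414) by 1.12 (SE 0.20); the ANXA1 call was lost without WT library 2 or 3 (adjusted p = 0.0696 and 0.0632). Genes of G2 and M were lower in 18 of 30 cases and higher in 0 (22 adjusted over the list alone; adjusted p = 2.49e-20; adjusted p = 0.155 with an estimated correlation), and heat shock genes were higher in 9 of 22 and lower in 1 (13 and 2 adjusted over the list alone), with HSPH1 at 0.78. Testing heat shock genes by camera gave adjusted p = 8.96e-07 (adjusted p = 0.476 with an estimated correlation). Ribosomal protein genes had a median of 0.09 and 1 of 77 was called, RPS3 at 0.38, a call lost without WT library 2 or 3 or D247A library 3 (adjusted p = 0.104, 0.0521 and 0.0653; 1 adjusted over the list alone; adjusted p = 0.00770; adjusted p = 0.955 with an estimated correlation). In all 2219 genes passed, 919 higher and 1300 lower in D247A (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 816 without WT library 2, 1387 without WT library 3 and 1231 without D247A library 2. Of the 3488 WT-selective genes, 1437 (41.2%) were called in D247A vs WT against the WT direction, and 746 (21.4%) were called in D247A vs GFP in the WT direction. These counts share WT or GFP libraries with the choice of the list; in D247A vs FL, which shares the FL libraries with it, 253 (7.25%) were called in the WT direction. Of 32 lists 10 passed camera, 8 up and 2 down, and 0 with an estimated correlation.

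R151A and FL were not told apart by this test, with 0 genes past the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg; smallest adjusted p = 0.148), 476 genes at an unadjusted p under 0.05 and 0 genes by limma-voom. DESeq2 called 6 genes. For HSPA6 the log2 fold change was -2.44 (SE 0.36), at 5.21 ± 1.35 against 28.2 ± 4.67 CPM, with an adjusted p of 0.289, while CCN1 had 0.21 (SE 0.15) and KIF20A 0.04 (SE 0.13); these 3 genes were chosen after their values were seen. Of 32 lists 5 passed camera, 4 up and 1 down, with 0 at an estimated correlation and 0 of their genes called; the median was 0.10 for ribosomal protein genes. Tested as a list, ribosomal protein genes had adjusted p = 9.63e-13 (adjusted p = 0.823 with an estimated correlation). In simulated libraries of these 2 groups, the test recovered 12% of 50 genes at the smallest change simulated. It recovered 82% of 50 changed 1.5-fold and 98% of 50 changed 2-fold, among 23423 tested. The simulation changed only genes at a mean CPM of at least 5 and drew each gene and library independently. Its rates may be too high for the real libraries, where HSPA6 was not called at -2.44. The 0 calls therefore do not show that R151A and FL lack differences of this size.

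D247A differed from FL in 493 genes, 250 higher and 243 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). CTSK was higher by a log2 fold change of 2.93 (SE 0.26, adjusted p = 1.89e-06), KCND1 by 2.92 (SE 0.21), PKNOX1, a homeobox transcription factor, by 1.46 (SE 0.12), SHOX2 by 1.40 (SE 0.15) and SGK1, a serum-regulated kinase, by 1.36 (SE 0.19). SRSF3 was higher by 1.04 (SE 0.09). RFX3, a transcription factor of ciliated cells, was lower, at -1.04 (SE 0.17), FBXW9, an F-box protein, at -1.01 (SE 0.14), MVP, the major vault protein, at -0.94 (SE 0.13) and ZNF767P at -0.93 (SE 0.15). The unfolded protein response list was lower, with 2 of 22 genes called (4 adjusted over the list alone; adjusted p = 4.22e-06; adjusted p = 0.515 with an estimated correlation), including HYOU1 at -0.48. The HYOU1 call was lost without any 1 of the 6 libraries (adjusted p from 0.0578 to 0.182). The count was 201, 243 and 121 without FL libraries 1, 2 and 3, and 221 and 224 without D247A libraries 2 and 3; DESeq2 called 1081 genes. Camera called 12 lists, 3 up and 9 down, and 0 with an estimated correlation. Among the 3 were the epithelial markers, with a median of 0.48 and 1 of 8 higher (1 adjusted over the list alone; adjusted p = 0.0275; adjusted p = 0.515 with an estimated correlation).

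The 2 single-residue variants differed from each other in 1282 genes, 454 higher and 828 lower in R151A (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). CTSK was lower in R151A at a log2 fold change of -3.07 (SE 0.27, adjusted p = 1.47e-06), KCND1 at -3.05 (SE 0.21), HSPA6 at -2.19 (SE 0.36), PKNOX1 at -1.44 (SE 0.12), NCOA5 at -1.40 (SE 0.25) and SRSF3 at -1.003 (SE 0.09). WWTR1, a coactivator of the Hippo pathway, was higher by 0.89 (SE 0.16), NEK6, a mitotic kinase, by 0.89 (SE 0.15), FBXW9 by 0.88 (SE 0.14), P4HA1 by 0.88 (SE 0.20) and GFRA1, a growth factor receptor, by 0.88 (SE 0.16). Genes of the unfolded protein response were higher in R151A in 6 of 22 cases (14 higher and 1 lower adjusted over the list alone), with CALR, an ER chaperone, at 0.52 (adjusted p = 1.52e-09; adjusted p = 0.294 with an estimated correlation), and 5 of 35 interferon-response genes were lower (6 adjusted over the list alone), with IFIT5 at -1.05. In the camera test, interferon-response genes had adjusted p = 1.21e-04 (adjusted p = 0.294 with an estimated correlation). The call of P4HA1 was lost without any 1 of the 6 libraries (adjusted p from 0.0533 to 0.0827). Autophagy genes went both ways, 2 higher and 3 lower of 37 (7 and 3 adjusted over the list alone), with ULK1 at -0.90 and LAMP1 at 0.48 (list adjusted p = 0.120). The count was 443, 446 and 667 without R151A libraries 1, 2 and 3 and 646 and 630 without D247A libraries 1 and 2; DESeq2 called 2019 genes. Lists past the camera threshold numbered 15, 11 up and 4 down, with 0 at an estimated correlation. Epithelial markers were among the 4, with a median of -0.72 and 2 of 8 lower (4 adjusted over the list alone; adjusted p = 0.0183; adjusted p = 0.294 with an estimated correlation).

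**Figure D4:**
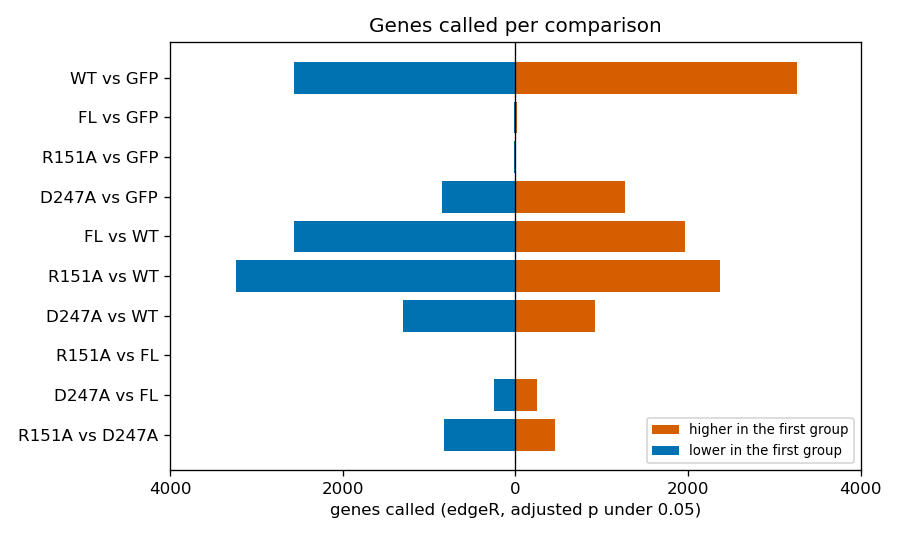
Genes called in each of the 10 comparisons by edgeR (x axis; bars to the right are higher and bars to the left lower in the first group named). WT vs GFP has 3266 higher and 2568 lower, D247A vs GFP 1268 and 849, and R151A vs FL 0.

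The share of the WT response that each variant kept was measured on genes called in WT vs GFP from other libraries than those used to measure it, with TARDBP left out. D247A kept 26.6% (28.8% ± 6.63, mean ± SD over n = 3 libraries; 20.7 to 40.4% over 9 choices of held-out libraries, with 2771 to 6413 genes). FL kept 1.58% (2.58% ± 8.21, n = 3; -7.17 to 16.02%), and R151A -8.41% (-7.47% ± 5.03, n = 3; -23.6 to 7.53%), where a negative share means a change on balance opposite to that of WT. The D247A libraries, at 24.5 to 36.5%, lay above those of FL, at -5.96 to 10.4%, and of R151A, at -10.7 to -1.67%; a two-sided exact permutation test gave p = 0.1 for each difference, the smallest that 3 libraries against 3 allow. The difference between FL and R151A had p = 0.2 in the same exact permutation test. Each share is an average over genes. Of 2116 genes called in D247A vs GFP with TARDBP left out, 284 were also called in D247A vs WT in the same direction. In those genes D247A lay further from GFP than WT did.

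**Figure D5:**
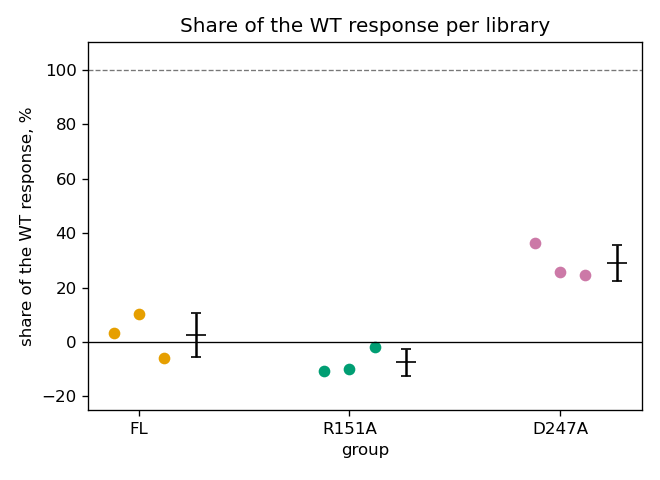
Share of the WT response in percent (y axis) in each library of FL, R151A and D247A, with the mean and SD (n = 3) as a bar beside the points and a dashed line at 100%, the WT response itself. The D247A libraries lie between 24.5 and 36.5%, and those of FL and R151A between -10.7 and 10.4%.

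WT and D247A shared 794 genes called higher than GFP, where independent lists would share 172.8, and 605 called lower, where 91.1 would be shared; 7 and 12 were called in opposite directions. With TARDBP left out, FL and R151A shared 6 higher genes, 5 without AC012485.1, and 4 lower, where independent lists would share 0.01 each. WT and FL shared 13 higher genes, AC012485.1 among them, and 9 lower, where 2.59 and 1.5 would be shared. WT and R151A shared 7 higher, AC012485.1 among them, and 3 lower, where 1.09 and 1.07 would be shared. Opposite calls numbered 3 and 1 between WT and FL and 3 and 0 between WT and R151A. These expectations leave out the shared GFP libraries. In 20 simulations of unchanged groups against shared GFP libraries, FL and R151A shared 0 calls and WT and D247A at most 1. No simulated group had more than 2 calls, so hardly any could be shared. The simulations therefore cannot show how much overlap shared GFP libraries give between groups with many changed genes. Across 23940 genes, which are not independent replicates, the log2 fold changes against GFP had a Pearson correlation of 0.537 between WT and D247A, 0.355 between WT and FL, 0.208 between WT and R151A, 0.616 between FL and R151A, 0.57 between FL and D247A and 0.458 between R151A and D247A. In 100 simulations of unchanged groups against shared, simulated GFP libraries the correlation averaged 0.497, with 0.521 as the highest. Each gene was drawn independently, with library sizes of WT, FL and GFP only. GFP library 3, which stood apart, was not modelled, so the real shared libraries may give another value. The covariance was 0.186 between WT and D247A, 0.102 between WT and FL, 0.0588 between WT and R151A, 0.102 between FL and R151A, 0.115 between FL and D247A and 0.0917 between R151A and D247A, against 0.0645 in the simulations. Part of these overlaps may come from the shared GFP libraries. Of 2116 genes called in D247A vs GFP with TARDBP left out, 400 were also called in D247A vs FL in the same direction, a comparison without GFP libraries that uses the same D247A libraries. A single test over the 5 groups called 5879 genes by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p under 0.05), and 3683 without WT library 2.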

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

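Counts that moved by over 1.5 times are given here; the cause was not tested. In the fit of the 2 groups alone the counts were 3750 in WT vs GFP, 19 in FL vs GFP, 10 in R151A vs GFP, 804 in D247A vs GFP, 797 in D247A vs FL, 1937 in R151A vs D247A and 2 in R151A vs FL. With 1 surrogate variable they were 208 in FL vs GFP, 77 in R151A vs GFP, 3585 in D247A vs GFP, 3476 in D247A vs WT, 1331 in D247A vs FL, 2106 in R151A vs D247A and 1 in R151A vs FL. DESeq2 called 188 in FL vs GFP, 124 in R151A vs GFP, 1081 in D247A vs FL, 2019 in R151A vs D247A and 6 in R151A vs FL. Without a filter the counts were 55 in FL vs GFP, 49 in R151A vs GFP and 1 in R151A vs FL, and limma-voom called 11 in R151A vs GFP. Leaving out 1 library gave 3453 to 6087 in WT vs GFP, 11 to 390 in FL vs GFP, 11 to 428 in R151A vs GFP, 1032 to 2402 in D247A vs GFP, 2399 to 5160 in FL vs WT, 3223 to 5843 in R151A vs WT, 816 to 2768 in D247A vs WT, 121 to 376 in D247A vs FL, 443 to 985 in R151A vs D247A and 0 in each run of R151A vs FL. It gave 3683 to 7329 for any difference, 1753 to 4057 WT-selective genes, and shares of the WT response of -1.57 to 6.08% in FL, -10.6 to -4.93% in R151A and 25.0 to 29.3% in D247A. Of 185 named genes in their comparisons, 38 lost or gained the call under at least 1 alternative and 0 reversed; the others kept their direction and call under each. No scaling shifted the median of all genes by over 0.1. Of 118 pairs of a list and a comparison past the camera threshold, 0 changed the sign of their median under RLE, DESeq2 or with TARDBP left out. With an estimated correlation 1 list passed in FL vs GFP, 1 in R151A vs GFP and 0 in each other comparison. Lists called by fry numbered 12 in WT vs GFP, 1 in FL vs GFP, 1 in R151A vs GFP and 4 in D247A vs GFP. They numbered 11 in FL vs WT, 14 in R151A vs WT and 4 in D247A vs WT. In R151A vs D247A fry called 8, and it called 0 in R151A vs FL and in D247A vs FL. The libraries are listed in 3 sets of 5, 1 of each construct, and the labels do not say that a set is a batch. Libraries of 1 set in different groups deviated from their group means with a median correlation of 0.249 (-0.174 to 0.574, 23 of 30 pairs over 0.1; -0.123 between sets), and 12 of 15 correlated best with their own set, a hint from the data and not the design. The deviations of a group sum to 0 for each gene, so the value between sets adds no separate evidence. A fit with the set as a replicate block, chosen after seeing the data, called 100 genes in FL vs GFP, 87 in R151A vs GFP, 1018 in D247A vs FL, 2068 in R151A vs D247A and 4 in R151A vs FL, and the other counts stayed within 1.5 times.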

Other observations

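The tests of the transgene level, of 1-exon genes against expression level, length and GC content, and of end-processing genes were chosen after the result was seen, and the zinc finger, 1-exon and end-processing gene sets were drawn up after seeing the data.

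Protein-coding genes with ZNF symbols, which encode zinc finger proteins, many of them transcription factors, were higher in WT and in D247A. Of 472 such genes, 167 (35.4%) rose and 21 fell in WT vs GFP, and 103 (21.8%) rose and 9 fell in D247A vs GFP (edgeR's quasi-likelihood test, Benjamini-Hochberg). Among coding genes of at least 5 exons, 16.2% rose in WT vs GFP and 7.56% in D247A vs GFP. In FL vs GFP and R151A vs GFP 0 zinc finger genes were called. This says little about the set, since only 0.14% and 0.08% of all genes were called there. In R151A vs D247A 7 were higher and 107 lower. The camera adjusted p over 60 set tests was 3.97e-08 in WT vs GFP and 5.28e-13 in D247A vs GFP (adjusted p = 0.184 and 0.129 with an estimated correlation). The set also passed camera as higher in FL vs GFP, with a median of 0.061 (adjusted p = 0.0208, and 0.468 with an estimated correlation). It did not pass in R151A vs GFP (camera, adjusted p = 0.761). Protein-coding genes with 1 exon were higher in WT than in GFP in 107 of 418 cases and lower in 47 (camera, adjusted p = 0.0111; adjusted p = 0.273 with an estimated correlation).

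The response was large in WT, with 5834 genes called, and small in FL, with 34, and R151A, with 19; without GFP library 3, which stood apart from the other GFP libraries, the counts were 5494, 390 and 428. The level of the transgene mRNA does not account for this: the 5 FL and R151A libraries whose TARDBP share reached that of the lowest WT library showed at most 10.42% of the WT response. Depth does not account for it either, since thinning every library to the lowest total, 51676824 counts, left 5661 genes in WT vs GFP, 37 in FL vs GFP and 23 in R151A vs GFP. The level of the TDP43 protein was not measured here and stays open, as does the loss of RNA binding, the biological difference that the design names for FL.

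The change from GFP to WT in log2 expression was higher for genes of 1 exon than for genes of at least 5 exons, by 0.175 (SE 0.064 between libraries) as a difference of means and 0.207 (SE 0.056) of medians. After adjustment for expression level, transcript length and GC content it was 0.158 (SE 0.033), above 0 by more than 2 SE. It exceeded 50% of the difference of means by more than 2 SE but not 50% of the difference of medians, so these features may account for part of the pattern, and how much stays open. Olfactory receptor genes, 66 with few counts and not limited to 1 exon, went from 0.021 ± 0.00212 CPM per kb in GFP to 0.0314 ± 0.00687 in WT (mean ± SD, n = 3). Their gain of 0.0104 (SE 0.00415) was above 0 by more than 2 SE, a loose bound with 3 libraries per group. It was small beside 0.114, the median gain of expressed 1-exon genes. By size this argues against DNA carried into the libraries as the main source of the pattern in WT, while a part stays open. The libraries held 0.0188 to 0.02302 CPM per kb in GFP and 0.02388 to 0.03735 in WT. They held 0.01362 to 0.02019 in FL, 0.01695 to 0.02145 in R151A and 0.01959 to 0.02507 in D247A. Across constructs the receptor genes thus went broadly the way of the 1-exon genes. Each gene in the deposited counts had a sum of at least 2, so wholly silent receptor genes could not be used. The adjusted difference in the change from GFP was -0.063 in FL (SE 0.022), -0.081 in R151A (SE 0.02) and 0.085 in D247A (SE 0.016). As unadjusted differences of means these were -0.138 (SE 0.051), -0.143 (SE 0.051) and 0.016 (SE 0.057). The D247A difference thus stood out from 0 only after adjustment. The biological difference between the constructs stays open, as untested.

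The change from GFP in log2 expression was higher for zinc finger genes than for other coding genes, by 0.23 in WT (SE 0.057) and 0.252 in D247A (SE 0.022). After adjustment for expression level, transcript length, GC content and exon number the differences were 0.146 (SE 0.06) and 0.157 (SE 0.03). Both stayed above 0 by more than 2 SE but not above 50% of the unadjusted difference by that much, so these features may account for part of the pattern, and how much stays open. With 3 libraries per group 2 SE is a loose bound. The biological difference between the constructs stays open as well.

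PPP1R10, PCF11, ZC3H4 and INTS5, chosen after their values were seen, which act in transcription termination and 3' end formation, rose in WT vs GFP by 2.34, 1.07, 1.29 and 1.72. The hypothesis that other genes of 3' end processing and the Integrator complex rise with them was tested on 34 genes, whose median log2 fold change was 0.146, with 7 higher and 4 lower (camera, p = 0.0609; p = 0.235 with an estimated correlation), which leaves it open.

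When the 6 libraries of a comparison were split in 10 ways with TARDBP left out, the real split called 5832 genes in WT vs GFP and the highest other 164. The real split and the highest other called 32 and 0 in FL vs GFP, 18 and 0 in R151A vs GFP, 2119 and 0 in D247A vs GFP, 4534 and 0 in FL vs WT, 5609 and 0 in R151A vs WT, 2218 and 0 in D247A vs WT, 495 and 0 in D247A vs FL and 1281 and 0 in R151A vs D247A. In R151A vs FL all 10 splits called 0. With 10 splits the smallest share is 0.1, too few for a share under 0.05. For the test of any difference among the 5 groups, 1 of 100 groupings, the real one, called as many as 5877 genes. The highest other called 360, so a random grouping of these libraries is unlikely to call as many. The groupings did not keep the 3 sets of listing together. They also cannot separate the construct from how the libraries of a group were made.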
